A study of Mus musculus with 12 samples.

How the data were processed

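Lateral habenula punches, taken from 500 µm vibratome slices of C57BL/6 mice aged 9 weeks, gave 12 RNA-seq libraries: 4 from non-defeated, 4 from stress-susceptible and 4 from stress-resilient mice. Per the labels' protocols, RNA was isolated with a NucleoSpin RNA XS kit and 100 pg of it entered a SMART-Seq v4 Ultra Low Input kit, followed by the Low Input Library Prep Kit v2. Per the submitters' processing notes, reads were assigned to genes of GRCm38 (mm10) with featureCounts and tested with edgeR. Their versions, the aligner and the use of strand are not given in the sources used here. Groups were taken from the labels. Each library has 1 matching interaction ratio in the behaviour sheet, but the labels do not state in words that each library is a separate mouse. The p-values of single genes and of the exact permutation tests measure the spread between these samples.

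Per the file headers the 12 deposited columns hold read counts, but their values are CPM, reads per 1000000 reads of the table's genes, plus a constant of 0.006078. After subtracting it, 100% of values were whole multiples of 1 read within 0.001 read. Whole reads per gene were recovered from that, and 1 read stood for 0.0210 to 0.0300 CPM. The deposited log2 ratios of each pair of groups, the score (a likelihood ratio over the 3 groups), its p-value and FDR came with the same table, per the file headers. A correlation of each gene's CPM with the interaction ratio and its p-value were also deposited. The deposited interaction ratio of a social avoidance test has 1 value per mouse, and the sheet does not state what is divided by what. All of these are cited as the authors' deposited table.

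The table held 17416 genes after removal of 1 closing line without a gene. Identifiers were matched to GENCODE M21 for 17402 genes, and 14 had no match. Depth was 33.3 M to 47.7 M reads (M, 1000000 reads), so a level of 1 CPM stands for at least 33 reads. Pooled over all genes, and so weighted towards abundant ones, the lowest chi-square per degree of freedom between libraries of 1 group was 73.4, where counting error alone gives 1. It was not measured at 1 CPM. The first 2 principal components held 20% and 14.1% of the variance.

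The test written before the data were examined was edgeR's quasi-likelihood test on counts, with limma-trend in its place if the file held no raw counts. As the unit is CPM, limma-trend (limma 3.58.1, robust) was used on log2 of TMM-scaled CPM plus 1 (edgeR 4.0.16, R 4.3.3). A model of the group means over all 12 libraries gave 3 pairwise comparisons and the mean of both defeated groups against non-defeated mice. The filter (filterByExpr, minimum count 10) removed 305 genes and left 17111, and Benjamini-Hochberg adjusted p under 0.05 was called. Gene lists, 28 in all, were fixed beforehand and tested with camera on the log2 values, not on counts as first written, with a preset inter-gene correlation of 0.01. They were also tested with an estimated correlation and with fry, whose p asks whether genes of a list move one way on balance, and whose mixed p whether they change in either direction. Neither compares a list with other genes. Camera does, and with the preset correlation its p rests on the spread between genes, not on how a list varies between samples. A list's score in a library is the mean over members of the log2 level less the gene's mean. The interaction ratio, the mitochondrial share of reads and 5 genes chosen beforehand were compared with exact permutation tests, whose smallest possible p is 0.0286. The 5 genes were picked as nearest to the title of the series, so their choice may not be independent of these data.

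Genes were named by a rule set beforehand. Where fewer than 20 genes passed, these were all that passed and then those with the smallest p up to 20 (10 for all defeated mice), together with Pcsk5, Furin, Mmp2, Mmp14, Acan and up to 4 members with the smallest p from each list described. E2f8, Brs3 and Acan had groups without a read, and their fold is a bound against a floor of 3 reads pooled over that group. Correlated fold changes were set against 100 simulated sets of unchanged groups sharing the controls.

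The procedure was tested on simulated data made from the libraries' own levels and spread. Of genes changed 2-fold it recovered 14% to 18% and of those changed 4-fold 55% to 66%, and 2.5% to 6.67% of genes passed were false. The changed genes were drawn from those averaging at least 1 CPM, in 1 simulated set per comparison, so recovery of scarcer genes was not measured. A list raised by 1.5 times in all members was called with both correlations, with 0 other lists called. Genes were drawn independently of each other there, so this cannot show how often correlated genes give false list calls.

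Alternatives set beforehand were other size factors, DESeq2 1.42.0 and limma voom with sample quality weights on recovered reads, no filter or a stricter one, no robust step, only the groups compared, the replicate number as a block, the letter of the titles as a term and each library left out. The letter, H or N, stands in the second code of the titles and its meaning is not given. Chosen after seeing the data were edgeR's quasi-likelihood test on recovered reads, pseudocounts of 0.25 and 5 CPM, no composition scaling, mitochondrially encoded genes left out, the 3 libraries of lowest mean correlation left out, and all tests of the mitochondrial share. That edgeR test was the one first written for raw counts, and only its use on recovered reads was chosen later.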

Results

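Transcripts of the lateral habenula were profiled in 12 libraries from C57BL/6 mice aged 9 weeks, 4 from non-defeated mice, 4 from mice susceptible to social defeat and 4 from mice resilient to it. The lateral habenula is a small epithalamic nucleus that relays aversive signals to midbrain monoamine neurons. Total reads per library, counted over the 17416 genes of the table, ran from 33.3 M to 47.7 M (M, 1000000 reads). They averaged 43.4 ± 4.14 M in the non-defeated, 39.3 ± 3.36 M in the susceptible and 40.7 ± 5.27 M in the resilient group (SD, n = 4 each). Levels are given in CPM (reads per 1000000 reads) with trimmed-mean (TMM) scaling, and fold changes on the scale of log2(CPM + 1), which understates the change of genes with low counts. Reads were amplified without molecular identifiers, so floors of 3 reads cover counting error only. The SD and SE values come from the spread between libraries.

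The interaction ratio of a social avoidance test was 1.45 ± 0.322 in non-defeated, 0.500 ± 0.253 in susceptible and 1.43 ± 0.546 in resilient mice (SD, n = 4 each). It was lower in each susceptible mouse than in any mouse of the other groups (exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.0429 over 3 comparisons, for both; p = 0.0571 for medians, and against resilient mice without resilient replicate 4). Resilient and non-defeated mice differed by -0.0225 (exact permutation test, p = 0.914). The groups carry the names of the behaviour this test scores, so the low ratio of susceptible mice is by construction and is no separate finding.

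**Figure D1:**
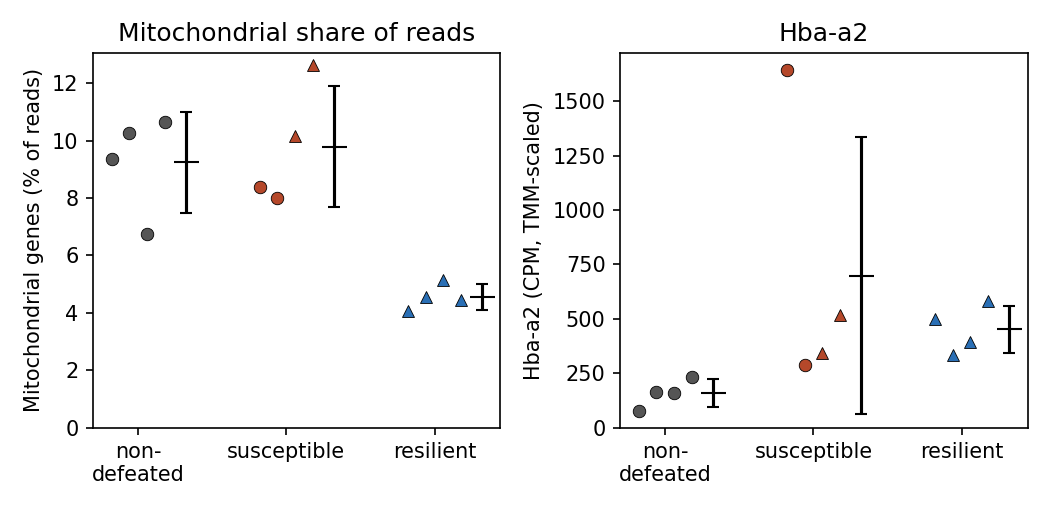
Share of reads from mitochondrially encoded genes (left, percent of reads) and level of Hba-a2 (right, CPM) in each of the 12 libraries, by group. Circles are libraries with the letter H in the title, triangles those with the letter N, and bars give the mean ± SD of 4 libraries. The 4 resilient libraries lie between 4.05% and 5.14%, under each of the other 8, and the highest Hba-a2 level, 1643 CPM, is in susceptible replicate 1.

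The comparison of susceptible with non-defeated mice asked which habenular transcripts go with avoidance after defeat, with convertase and matrix genes, the subject of the series, of first interest. Pcsk5, a proprotein convertase that cleaves precursor proteins after basic residues, stood at 6.11 ± 1.67 CPM in non-defeated and 19.7 ± 6.71 CPM in susceptible mice (SD, n = 4 each). Its log2 fold change was 1.50 ± 0.38 (SE), and each of the 4 susceptible libraries lay above each non-defeated one. Acan, the gene of the perineuronal net proteoglycan aggrecan, had no read in the 4 non-defeated libraries and 2, 140, 69 and 155 reads in the susceptible ones. That is at least 135-fold higher against a floor of 3 reads over the non-defeated group. The log2 fold change of Acan was 1.56 ± 0.42 (SE). Blood cell markers rose as a list (camera, adjusted p = 8.08e-08; adjusted p = 0.304 with an estimated correlation), with the alpha-globin gene Hba-a2 at 159 ± 65.0 CPM in non-defeated and 699 ± 638 CPM in susceptible mice (SD, n = 4 each; log2 fold change 1.87 ± 0.46, SE). Susceptible replicate 1 alone stood at 1643 CPM, and without it the susceptible mean of Hba-a2 was 384 CPM and the log2 fold change 1.33.

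Of 17111 genes tested with limma-trend, 0 passed a Benjamini-Hochberg adjusted p of 0.05, and the smallest adjusted p was 0.139. At an unadjusted p under 0.05 there were 606 genes, 298 higher and 308 lower. The edgeR quasi-likelihood test called 0 genes, limma voom with sample quality weights 0 and DESeq2 23. Values of the groups did not overlap for 380 genes, 2.22% of those tested, where chance gives 2.86%. For Pcsk5 (ENSMUSG00000024713, chromosome 19, 17432319 to 17837632 on GRCm38) and Acan (ENSMUSG00000030607, chromosome 7, 79053483 to 79115099) the adjusted p by limma was 0.998 for both, and by DESeq2 0.0595 for Pcsk5 and 0.00151 for Acan. Exact permutation tests gave p = 0.0286 for both, the smallest that 4 against 4 samples allow, and 0.214 after adjustment over 15 tests of 5 genes. For Acan that p rests on the 2 reads of susceptible replicate 1, fewer than the floor of 3, against 0 in each non-defeated library. These 5 genes were picked as nearest to the title of the series, and no adjustment over them or their lists alone covers that choice. In the authors' deposited table, whose test spans all 3 groups, the FDR was 0.164 for Pcsk5 and 0.0110 for Acan.

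**Figure D2:**
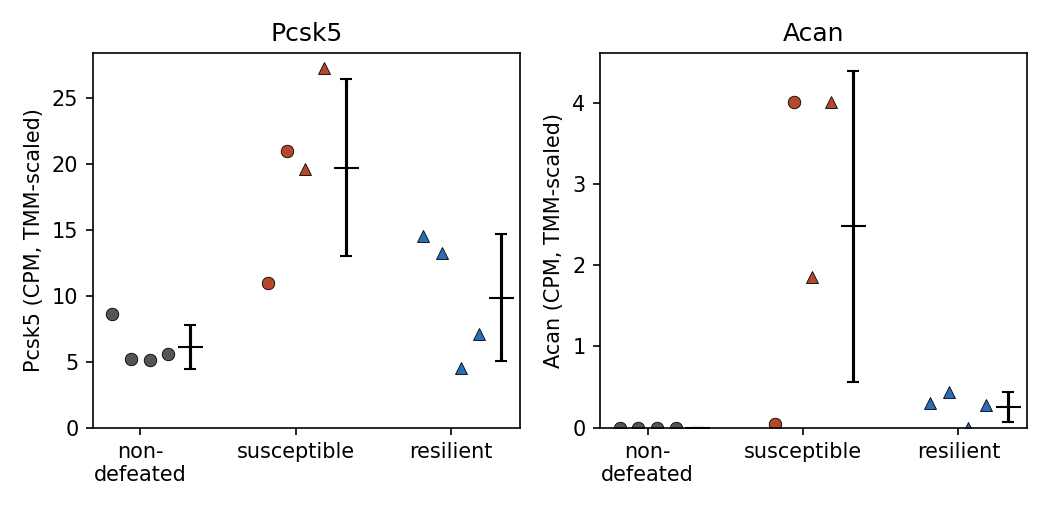
Levels of Pcsk5 (left) and Acan (right) in CPM in each of the 12 libraries, by group. Circles are libraries with the letter H in the title, triangles those with the letter N, and bars give the mean ± SD of 4 libraries. Pcsk5 averages 6.11 CPM in non-defeated, 19.7 CPM in susceptible and 9.85 CPM in resilient mice, and Acan 0, 2.48 and 0.252 CPM.

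Among the 9 proprotein convertases, all measured, 0 rose over all genes tested and Pcsk5 alone rose when p was adjusted over the list alone (limma, adjusted p = 0.0134). The log2 fold changes of Pcsk4, Furin and Pcsk7 were 0.83 ± 0.41, -0.69 ± 0.42 and -0.38 ± 0.35 (SE), and none passed. The median over the list was -0.10, the mean 0.05, and camera, which compares a list with all other genes, gave an adjusted p of 0.979 towards lower levels. Of 20 perineuronal net genes, all measured, 0 passed over all genes and Acan alone rose adjusted over the list alone (limma, adjusted p = 0.0456). Their median was -0.04, their mean 0.03 and the camera adjusted p 0.979. Of 25 metalloproteinase, ADAM and inhibitor genes 24 were measured and 0 passed either way, with a median of 0.05, a mean of -0.01 and a camera adjusted p of 0.979. Mmp2 and Mmp14, matrix metalloproteinases, had log2 fold changes of 0.48 ± 0.70 and 0.38 ± 0.44 (SE). Of 31 collagen, laminin and other matrix genes 29 were measured and 0 passed, with a median of 0.13 and a camera adjusted p of 0.533. Lamc1 and Col3a1 stood highest among them by p, at 1.58 ± 0.58 and 1.41 ± 0.54 (SE).

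Of 8 blood cell markers 6 were measured and 5 had positive fold changes, with a median of 1.75. Over all genes 0 members passed, and 5 rose adjusted over the list alone. Hba-a1 was at 1.70 ± 0.45, Hbb-bs at 1.66 ± 0.54 and Alas2, the first enzyme of heme synthesis in red cell precursors, at 2.06 ± 0.58 (SE). Hba-a1 and Hba-a2, like Hbb-bs and Hbb-bt, are near-identical copies that share reads, so their separate levels are uncertain. The blood score, the mean log2 level of the list less each gene's mean, ran from -1.50 to -0.61 in non-defeated libraries and reached 1.99 in susceptible replicate 1. Cytosolic ribosomal protein genes fell as a list: 33 of 35 were negative, with a median of -0.14 (camera, adjusted p = 7.58e-05; adjusted p = 0.910 with an estimated correlation). No member passed over all genes or over the list alone, and Rps27, Rps2 and Rps23 stood at -0.74 ± 0.33, -0.31 ± 0.16 and -0.61 ± 0.36 (SE). Without non-defeated replicate 4 the ribosomal call ended (adjusted p = 0.761), and without the 3 libraries of lowest mean correlation, non-defeated replicates 3 and 4 and resilient replicate 4, the list turned direction (0.815). The number of lists called, 2, became 6 without non-defeated replicate 1 or 2, 7 without susceptible replicate 1 and 8 without susceptible replicate 4.

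Immediate early genes, which report recent neuronal firing, were not called (19 of 21 measured, median -0.12, camera adjusted p = 0.115). Fos and Junb among them had log2 fold changes of -1.44 ± 0.67 and -0.86 ± 0.37 (SE). Of the 25 habenular excitability genes, all measured, 0 passed (median 0.10, camera adjusted p = 0.758), with Kcnj3, a G-protein-gated potassium channel subunit, at -0.87 ± 0.28. The other genes with the smallest p did not pass either. Higher in susceptible mice were Gm4793 at 2.25 ± 0.35, Anks6 at 2.06 ± 0.53, Capn3 at 1.98 ± 0.44, Terb1 at 1.90 ± 0.47, Zfp78 at 1.87 ± 0.41, Pcdhb11 at 1.70 ± 0.43, Alkbh4 at 1.19 ± 0.31 and Fig4 at 1.01 ± 0.26. Lower were Etv6 at -2.05 ± 0.48, Glis3 at -1.96 ± 0.40, Shq1 at -1.83 ± 0.38, Gm16487 at -1.63 ± 0.36, Tshb at -1.44 ± 0.33, Tcim at -1.24 ± 0.32, Usp31 at -1.24 ± 0.29, Nfatc2ip at -1.22 ± 0.26 and Kat6a at -1.19 ± 0.25 (log2, SE). Brs3, a bombesin receptor-like G-protein-coupled receptor, averaged 2.02 ± 0.353 CPM in non-defeated mice (SD, n = 4) and had no read in susceptible ones, at least 107-fold lower against a floor of 3 reads over the susceptible group. Gm4793 is annotated antisense, and without stated use of strand its reads cannot be told from those of the gene on the other strand.

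The comparison of resilient with non-defeated mice asked which transcripts differ in defeated mice that do not avoid others. Mitochondrial transcripts were lower in resilient mice. The small mitochondrial ribosomal RNA, mt-Rnr1 (ENSMUSG00000064337, chromosome M, 70 to 1024), fell by 1.24 ± 0.16 (SE, log2), from 2736 ± 526 to 1150 ± 176 CPM (SD, n = 4 each; limma-trend, adjusted p = 0.0276). Mitochondrially encoded genes gave 9.24% ± 1.76 of reads in non-defeated and 4.55% ± 0.450 in resilient mice (SD, n = 4 each). Each resilient library lay below each non-defeated one (exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.0429 over 3 comparisons; p = 0.0571 without any 1 resilient library or for medians).

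All 13 protein-coding mitochondrial genes were measured and negative, with a median of -0.96 (camera, adjusted p = 1.03e-28; adjusted p = 0.109 with an estimated correlation). None of the 13 passed over all genes tested, and all 13 fell adjusted over the list alone. Examples are the cytochrome oxidase genes mt-Co3 at -1.35 ± 0.24 and mt-Co2 at -1.54 ± 0.29, the complex I gene mt-Nd3 at -1.95 ± 0.38 and another, mt-Nd4, at -0.96 ± 0.18 (log2, SE), while the ATP synthase gene mt-Atp6 averaged 13500 CPM in non-defeated and 6796 CPM in resilient mice. The rotation test fry, which asks whether the genes of a list move one way on balance, gave the mitochondrial list an adjusted p of 0.0195, the only list it called of 28. Nuclear-encoded oxidative phosphorylation genes fell less, 27 of 30 negative with a median of -0.17 (camera, adjusted p = 0.000253; adjusted p = 0.783 with an estimated correlation). Cox7c and Cox8a had the smallest p of its members, at -0.78 ± 0.30 and -0.36 ± 0.17 (SE), and 0 members passed in either way. All 35 cytosolic ribosomal protein genes were negative, with a median of -0.40 (camera, adjusted p = 1.90e-23; adjusted p = 0.374 with an estimated correlation). Of these, 0 passed over all genes, and Rps2, at -0.79 ± 0.16, fell adjusted over the list alone.

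Blood cell markers rose here too as a list, 5 of 6 positive with a median of 1.36 (camera, adjusted p = 7.90e-05; adjusted p = 0.374 with an estimated correlation), 0 members over all genes and 5 adjusted over the list alone. Hba-a2 stood at 1.58 ± 0.46 and Alas2 at 1.89 ± 0.58 (log2, SE). Resilient replicate 4 had a blood score of 1.077 and the other resilient libraries -0.009 to 0.138, all above the highest non-defeated score of -0.61. Markers of the neighbouring medial habenula fell as a list, 10 of 13 negative with a median of -0.31 (camera, adjusted p = 0.00477; adjusted p = 0.476 with an estimated correlation). Over all genes 0 of them passed, and 2 fell adjusted over the list alone. These were Tac2, the neurokinin B precursor, at 57.0 against 12.3 CPM, and Chrna3, a nicotinic receptor subunit, at 45.4 against 8.13 CPM. Thalamus markers fell as a list, 12 of 14 negative with a median of -0.40 (camera, adjusted p = 0.00767; adjusted p = 0.716 with an estimated correlation). None of its members passed in either way, and Adarb1 stood at -0.66 ± 0.23 (SE). Non-defeated replicate 3 had the highest medial habenula score, 1.31, and non-defeated replicate 4 the lowest mean correlation with the other libraries, 0.932.

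Of 28 lists 6 were called, and lateral habenula markers were not among them (12 measured, 9 negative, median -0.09, camera adjusted p = 0.506). Syn2, a synaptic vesicle protein gene, rose adjusted over that list alone, at 1.21 ± 0.35 (SE). Glucocorticoid-induced genes changed, in either direction, by fry's mixed test (adjusted p = 0.026) and were not called by camera (adjusted p = 0.0766). Adjusted over the list alone, 2 of its 19 measured members fell and 1 rose, with 0 over all genes. The metallothionein genes Mt1 and Mt2 were at -0.76 ± 0.15 and -0.80 ± 0.24, and Klf9, a transcription factor gene induced by glucocorticoids, at 0.98 ± 0.31 (log2, SE). Of 14 heat shock and tissue-handling stress genes, Hspa8, a constitutive chaperone, rose adjusted over the list alone, at 0.54 ± 0.14 (SE), and the list was not called (camera adjusted p = 0.262). In the excitability list 0 passed in either way. Hcn2 and Hcn4, channels of the hyperpolarisation-activated current, were at 2.50 ± 0.93 and 1.25 ± 0.40 and the phosphatase gene Ppp2ca at 1.73 ± 0.68 (log2, SE). With the H or N letter of the titles as a term, fold changes turned to -1.09 for Hcn2, -1.13 for Ppp2ca, -0.20 for Klf9 and -0.18 for Syn2.

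Over all genes 1 of 17111 passed by limma-trend, mt-Rnr1, and 1222 had an unadjusted p under 0.05, 731 higher and 491 lower. Values of the groups did not overlap for 626 genes, 3.66% against 2.86% by chance. The edgeR quasi-likelihood test called 0, limma voom with sample quality weights 8 and DESeq2 91. Other genes with the smallest p included mt-Rnr2 at -1.14 ± 0.17, mt-Nd5 at -0.98 ± 0.20, mt-Nd6 at -0.94 ± 0.19, mt-Nd2 at -0.92 ± 0.19, Max at -1.92 ± 0.39, Aph1c at -1.55 ± 0.33, Brs3 at -1.39 ± 0.25, Ergic1 at -1.06 ± 0.19 and Vma21 at -0.75 ± 0.16. Higher among them were Sik3 at 1.65 ± 0.35 and Ctnnd2, a neuronal catenin, at 1.02 ± 0.20 (log2, SE). E2f8, a transcription factor of the cell cycle, had no read in non-defeated or susceptible mice and 1.77 ± 0.722 CPM in resilient ones (SD, n = 4), at least 105-fold higher against a floor of 3 reads over the non-defeated group. Pcsk5 was at 0.51 ± 0.38, Furin at -0.74 ± 0.42, Mmp14 at 0.71 ± 0.44 and Mmp2 at -0.04 ± 0.70 (log2, SE). Acan, with 13, 18, 0 and 10 reads in resilient libraries, was at least 14.6-fold higher pooled over the group than the floor of non-defeated ones. It did not pass, at a log2 fold change of 0.31 ± 0.42 (SE, limma adjusted p = 0.965, exact permutation test p = 0.143). With the title letter as a term Pcsk5 turned to -0.06 and Acan to -0.41.

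All non-defeated libraries carry the letter H and all resilient ones the letter N, so that difference rests on the susceptible group, which has both. With the letter as a term the number of genes passing became 0 (mt-Rnr1 at -1.47, limma adjusted p = 0.432), as it did without the robust step (-1.24, 0.0742) and with only these groups fitted (-1.25, 0.276). With that term the mitochondrial list kept its call (camera, adjusted p = 1.99e-31), while the medial habenula and thalamus calls ended (adjusted p = 0.25 for both). That number was also 0 without non-defeated replicate 1, 2 or 4, susceptible replicate 2 or 3 or resilient replicate 1 or 2, 2 without non-defeated replicate 3 or susceptible replicate 4 and 9 without resilient replicate 4. Calls also ended for oxidative phosphorylation without non-defeated replicate 3 (adjusted p = 0.0534), non-defeated replicate 4 (0.249) or resilient replicate 4 (0.574), and turned to higher levels without all 3 of these (2.33e-05), for the medial habenula without non-defeated replicate 3 (0.214) and for the thalamus without non-defeated replicate 4 (0.158).

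**Figure D3:**
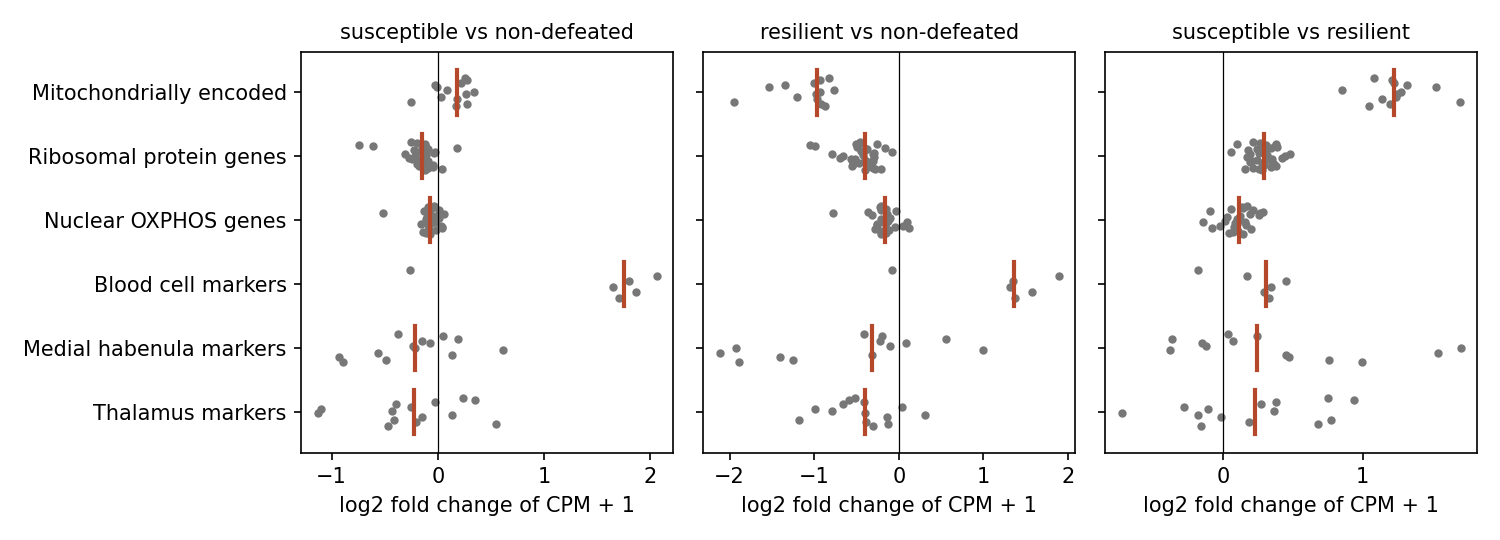
Log2 fold change on the scale of CPM + 1 of each measured member (grey points) of 6 gene lists in the comparisons of susceptible with non-defeated, resilient with non-defeated and susceptible with resilient mice. Red bars give the list's median. The mitochondrial median is 0.18 in the left panel, -0.96 in the middle and 1.23 in the right one, where all 13 members are positive.

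The comparison of susceptible with resilient mice asked what differs between defeated mice that avoid others and those that do not. Mitochondrial transcripts rose in susceptible against resilient mice. Both mitochondrial ribosomal RNAs passed the test, mt-Rnr1 at 1.18 ± 0.16 and mt-Rnr2 at 1.13 ± 0.17, as did mt-Nd6 at 1.27 ± 0.19, mt-Nd5 at 1.25 ± 0.20, mt-Atp6 at 1.23 ± 0.19, mt-Nd2 at 1.19 ± 0.19 and mt-Nd4 at 1.14 ± 0.18 (log2, SE; limma-trend, adjusted p from 0.0475 to 0.04999). Capn3, a calcium-dependent protease gene (ENSMUSG00000079110, chromosome 2, 120456019 to 120504913), rose by 2.77 ± 0.44 (SE, log2; limma adjusted p = 0.04999), with 7.15 ± 3.14 CPM in susceptible and 0.109 ± 0.127 CPM in resilient mice (SD, n = 4 each). The mitochondrial share of reads was 9.79% ± 2.11 in susceptible and 4.55% ± 0.450 in resilient mice (SD, n = 4 each). Each susceptible library lay above each resilient one (exact permutation test, 2-sided, p = 0.0286, adjusted p = 0.0429; p = 0.0571 for medians). Among libraries with the letter N the shares were 10.2% and 12.6% in the susceptible and 4.05% to 5.14% in the resilient group.

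All 13 protein-coding mitochondrial genes were positive with a median of 1.23, and 5 rose over all genes and 13 adjusted over the list alone (camera, adjusted p = 5.20e-45; adjusted p = 0.026 with an estimated correlation). It was the one list of 28 called with an estimated correlation, and fry gave it an adjusted p of 0.00708. Those short of the threshold over all genes were mt-Atp8 at 1.21 ± 0.20, mt-Co3 at 1.32 ± 0.24, mt-Co2 at 1.53 ± 0.29, mt-Co1 at 0.85 ± 0.18, mt-Nd1 at 1.05 ± 0.19, mt-Cytb at 1.08 ± 0.20 and mt-Nd4l at 1.24 ± 0.26, besides mt-Nd3. The nuclear genes Gm13340 and Gm13341, at 0.92 ± 0.16 and 1.39 ± 0.26, are copies of mitochondrial sequence that can share its reads, so their values are uncertain. Ribosomal protein genes rose as a list, 35 of 35 positive with a median of 0.29 (camera, adjusted p = 2.15e-14; adjusted p = 0.536 with an estimated correlation), and oxidative phosphorylation genes by less, 26 of 30 with a median of 0.11 (camera, adjusted p = 0.0190; adjusted p = 0.809 with an estimated correlation). None of their members passed over all genes or over the list alone; Rps2 stood at 0.48 ± 0.16 and Cox8a at 0.28 ± 0.17 (SE).

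Myelin genes rose as a list, 15 of 16 positive with a median of 0.24 (camera, adjusted p = 0.000591; adjusted p = 0.536 with an estimated correlation). Cldn11, a tight junction component of the myelin sheath, was at 0.59 ± 0.21 (SE). Microglia markers rose as a list, 11 of 14 positive with a median of 0.29 (camera, adjusted p = 0.0190; adjusted p = 0.536 with an estimated correlation), and Siglech stood at 1.11 ± 0.33. Heat shock and tissue-handling stress genes fell as a list, 11 of 14 negative with a median of -0.19 (camera, adjusted p = 0.0385; adjusted p = 0.335 with an estimated correlation), and Hspa8 was at -0.44 ± 0.14. In these 3 lists 0 members passed over all genes or over the list alone. Mt1 rose adjusted over the glucocorticoid list alone, at 0.57 ± 0.15 (SE). Pcsk5 was at 0.99 ± 0.38, Acan at 1.24 ± 0.42, Furin at 0.05 ± 0.42, Mmp2 at 0.51 ± 0.70 and Mmp14 at -0.32 ± 0.44 (log2, SE), and none passed. Exact permutation tests gave p = 0.0857 for Pcsk5 and 0.114 for Acan, 0.321 and 0.343 after adjustment over the 15 tests. Outside the mitochondria E2f8, absent from susceptible libraries, was at least 95.1-fold lower in them, Tnfrsf8 at -2.12 ± 0.44 and 4930525G20Rik at 2.03 ± 0.44 (log2, SE). Like Gm4793, 4930525G20Rik is annotated antisense, and its reads cannot be told from those of the gene on the other strand.

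Of 17111 genes 8 passed by limma-trend, all higher in susceptible mice, and 601 had an unadjusted p under 0.05, 272 higher and 329 lower. Values of the groups did not overlap for 419 genes, 2.45% against 2.86% by chance. The edgeR quasi-likelihood test called 0, limma voom with sample quality weights 16 and DESeq2 38. The number was 0 without any 1 susceptible or resilient library, without non-defeated replicate 1 or 2, without the robust step, with only these groups fitted or with a pseudocount of 5 CPM, 1 with a pseudocount of 0.25 CPM and 2 without non-defeated replicate 4. It was 9 with the title letter as a term, with median-of-ratios factors, with no filter or with the strict filter, and 10 without non-defeated replicate 3. With mitochondrial genes left out it was 0, so Capn3, the only nuclear gene called, did not pass without them. Capn3 lost its call in 22 of the alternative settings and kept it in 6. The 6 lists called became 10 without resilient replicate 1 and 2 without resilient replicate 4. Without resilient replicate 4 the oxidative phosphorylation list turned direction (adjusted p = 0.847), and the myelin (0.0777), microglia (0.163) and heat shock (0.138) calls ended. The microglia call also ended without susceptible replicate 3 (0.22) or resilient replicate 2 (0.0522), the oxidative phosphorylation call without susceptible replicate 2 (0.0987) or 4 (0.313) or composition scaling (0.0739), and the heat shock call without non-defeated replicate 3 (0.0513), susceptible replicate 3 (0.114) or 4 (0.202) or resilient replicate 2 (0.0550) or 3 (0.129).

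All defeated mice, the mean of the susceptible and resilient groups, were compared with non-defeated mice to ask what the groups share after defeat. Blood cell markers rose as a list, 5 of 6 positive with a median of 1.56 (camera, adjusted p = 2.51e-07; adjusted p = 0.422 with an estimated correlation), 0 members over all genes and 5 adjusted over the list alone. Hba-a2 was at 1.72 ± 0.40 and Alas2 at 1.98 ± 0.50 (log2, SE). Susceptible replicate 1 and resilient replicate 4 had the highest blood scores of their groups, 1.99 and 1.077. Ribosomal protein genes fell, 34 of 35 negative with a median of -0.28 (camera, adjusted p = 3.22e-16; adjusted p = 0.586 with an estimated correlation), 0 over all genes and 1, Rps2, adjusted over the list alone. Mitochondrially encoded genes fell, 13 of 13 negative with a median of -0.36 (camera, adjusted p = 1.46e-10; adjusted p = 0.586 with an estimated correlation), 0 over all genes and 3 adjusted over the list alone, mt-Nd3, mt-Co3 and mt-Co2. This is not shared by the groups: 13 of 13 were negative in resilient mice, but 10 of 13 positive in susceptible ones (median 0.18). Oxidative phosphorylation genes fell, 27 of 30 negative with a median of -0.12 (camera, adjusted p = 0.00352; adjusted p = 0.876 with an estimated correlation). The same held for markers of the medial habenula, 10 of 13 negative with a median of -0.19 (camera, adjusted p = 0.0138; adjusted p = 0.647 with an estimated correlation), and the thalamus, 12 of 14 negative with a median of -0.26 (camera, adjusted p = 0.0172; adjusted p = 0.876 with an estimated correlation). In these 3 lists 0 members passed in either way; Cox7c was at -0.65 ± 0.26, Tac2 at -1.39 ± 0.41 and Adarb1 at -0.53 ± 0.20 (log2, SE).

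By limma-trend 0 of 17111 genes passed (smallest adjusted p = 0.114), and 979 had an unadjusted p under 0.05, 579 higher and 400 lower. Values of the groups did not overlap for 65 genes, 0.380% against 0.404% by chance. The edgeR quasi-likelihood test called 0, limma voom with sample quality weights 0 and DESeq2 35. The genes with the smallest p were Brs3 at -1.49 ± 0.22, Nfatc2ip at -1.21 ± 0.23, Gm4793 at 1.52 ± 0.30, Abcc4 at 1.91 ± 0.39, Gm16487 at -1.50 ± 0.31, Pcdhb11 at 1.83 ± 0.38, mt-Rnr1 at -0.65 ± 0.14, Ctnnd2 at 0.81 ± 0.18, Tshb at -1.31 ± 0.29 and Brd7 at 0.62 ± 0.14 (log2, SE). Pcsk5 was at 1.01 ± 0.33, Acan at 0.93 ± 0.36 (DESeq2, adjusted p = 0.0105), Furin at -0.72 ± 0.37, Mmp2 at 0.22 ± 0.61 and Mmp14 at 0.55 ± 0.38. The oxidative phosphorylation call ended without non-defeated replicate 3 (adjusted p = 0.344), non-defeated replicate 4 (0.925) or resilient replicate 4 (0.324), and its direction turned without all 3 (4.35e-08), while the medial habenula call ended without non-defeated replicate 3 (0.636). The thalamus call ended without non-defeated replicate 2 (0.0700) or 4 (0.457) or susceptible replicate 2 (0.141) or 3 (0.105), and it and the medial habenula call ended with the title letter as a term (0.273 for both).

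Across 17111 genes, which are not independent replicates, the fold changes of susceptible and resilient against non-defeated mice correlated at r = 0.602. Both share the 4 control libraries, and 100 simulated sets of unchanged groups gave a mean of 0.499, from 0.482 to 0.519. Genes were drawn independently in these sets, so that range leaves out the spread that correlated genes add. The covariance was 0.108 against a simulated 0.0947, a difference of 0.0139. With the controls split between the comparisons, the mean correlation over 6 splits was 0.064. An FDR under 0.05 over the 3 groups was given by the authors' deposited table for 51 genes, of which 14 were mitochondrially encoded and 16 had a group without a read. Its smallest FDR was that of mt-Rnr1, 7.886e-05.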

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

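All tests of explanations here were chosen after the results were seen, except that of residual red blood cells, whose list and outcome were written beforehand.

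Mitochondrially encoded transcripts were lower in resilient mice than in both other groups. If the letter of the titles set this share, susceptible libraries with the letter N would lie near the resilient ones, but the lower of them lay 5.03 percentage points above the highest resilient library. A bias by transcript length as the whole of this was argued against by 10000 lists of nuclear genes matched on length. Their lowest median was -0.38 against -0.96, although the 1576 genes to draw from are less abundant (matched median 7.88 against 12.06 log2). The median of these lists' medians was -0.13, where that over all genes was 0.02, so a smaller bias of this kind is not excluded. The ribosomal and nuclear oxidative phosphorylation lists were not set against matched lists. With the medial habenula and thalamus scores as covariates the mitochondrial difference of resilient from non-defeated mice was -1.22 ± 0.22, against -1.10 ± 0.21 without them (log2, SE), which argues against these neighbours as the source. Handling stays open, as heat shock and tissue-handling stress genes were lower in susceptible than resilient mice (median -0.19, camera adjusted p = 0.0385; adjusted p = 0.335 with an estimated correlation), and RNA quality and a difference tied to resilience itself, a hypothesis, were not tested.

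Hemoglobin transcripts were higher in both defeated groups only as part of the blood list, with 0 members passing over all genes and the list call lost in both (camera, adjusted p = 0.304 and 0.374 with an estimated correlation). Residual red blood cells may account for it: a separate erythroid list, 7 of 17 genes measured, had a median log2 fold change of 0.22 in susceptible and 0.21 in resilient mice, the direction predicted (camera of limma, unadjusted p of 0.0681 and 0.0467, with under 0.05 in at least 1 asked for). That evidence is weak, since the tissue expresses 5 of the 7 at 5 CPM or more in non-defeated mice, and members differed, with 0.09 for Bpgm (118 CPM there) and 1.28 for Ube2l6 (5.88 CPM). More vessels cannot be told apart from this over both groups: the blood median lay above the endothelial one by 1.46 in susceptible mice, over 2 times the member SE of 0.68, but by 0.91 in resilient mice, under 2 times that SE, where resilient replicate 4 had an endothelial score of 2.15 and the other libraries at most 0.29. The letter cannot be told apart either: the call held with it as a term (camera, adjusted p = 3.44e-08 and 6.22e-05) and susceptible scores averaged 0.87 with H and 0.27 with N, against a rise with N, but the lower letter H library lay only 0.36 above the highest non-defeated one (SD 0.41), and the score differences with that term, 1.77 ± 0.61 and 1.84 ± 0.87, were 0.65 ± 0.52 and 0.72 ± 0.66 (SE) without susceptible replicate 1, while a biological change after defeat stays open as untested.

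Pcsk5 and Acan were higher in susceptible mice. A letter batch is argued against for Pcsk5, whose susceptible libraries lay at least 2.38 CPM above those of the other group with the same letter. For Acan it cannot be told apart, because that gap was 0.0458 CPM, set by the 2 reads of susceptible replicate 1. Selection among many genes could account for Pcsk5 by itself: 16 genes had a p at or below its own, where chance gives 25.5. Although Pcsk5 was 1 of 5 genes chosen beforehand, they were picked as nearest to the title of the series. That choice may not be independent of these data. A change tied to susceptibility stays open.

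Splits of the same libraries into groups of the same sizes, the real split counted among them, did not exclude chance for any count above 0. For genes called, 2 of 35 splits gave as many as the real 1 for resilient against non-defeated mice (highest other 2) and 2 of 35 as many as 8 for susceptible against resilient (highest other 147). With a real count of 0, all of them, 35 of 35 for susceptible against non-defeated (highest other 40) and 100 of 100 for all defeated mice (highest other 2), give as many by construction and decide nothing. The single splits with 40 and 147 genes point to some structure of the samples, whose cause was not tested. The 147-gene split set susceptible replicates 1, 2 and 4 and resilient replicate 4 apart. On the first principal component these lay from -62.28 to 2.219, and the other susceptible and resilient libraries from 17.96 to 55.16. The sides of the 40-gene split overlapped there. For lists called, the numbers were 31 of 35 for a real 2 (highest other 14) for susceptible against non-defeated, 25 of 35 for 6 (13) for resilient against non-defeated, 15 of 35 for 6 (11) for susceptible against resilient and 42 of 100 for 6 (12) for all defeated mice.

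Levels differed between susceptible and resilient mice, by the limma test of their difference, for mt-Rnr1 (log2 1.18), mt-Rnr2 (1.13), mt-Nd6 (1.27), mt-Atp6 (1.23), mt-Nd4 (1.14), mt-Nd5 (1.25), mt-Nd2 (1.19) and Capn3 (2.77). Their limma adjusted p ran from 0.04745 to 0.04999. The number of genes passing was 0 without any 1 susceptible or resilient library and by edgeR's quasi-likelihood test. Capn3, the only nuclear gene among them, did not pass with mitochondrial genes left out. By camera, levels differed for the mitochondrial (adjusted p = 5.20e-45), ribosomal (2.15e-14), myelin (0.000591), microglia (0.0190), oxidative phosphorylation (0.0190) and heat shock (0.0385) lists. With an estimated correlation the mitochondrial call held (adjusted p = 0.026), and the others were lost, at 0.536 for ribosomal, myelin and microglia, 0.809 for oxidative phosphorylation and 0.335 for heat shock.

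Single samples far from the 3 others of their group, by the gap over the group's range, were found in 24 of 286 groups with more than 1 library above 0, where chance gives about 1 in 20, or 14. In 4 more groups the other 3 libraries were at 0, which fixes the measure at 1, so these say nothing of a sample apart: Gm4793 in non-defeated replicate 3, Tshb in susceptible replicate 3, Tcim in susceptible replicate 2 and Gm16487 in susceptible replicate 4. Resilient replicate 4 stood highest for Lamc1 (0.901), Hbb-bt (0.956), Rps27 (0.922), Abcc4 (0.842), the blood score (0.865) and the interaction ratio, 2.24 against 1.08 to 1.20 (0.897). Susceptible replicate 1 stood highest for Hba-a1 (0.839), Alas2 (0.889) and Nfatc2ip (0.910) and replicate 3 for Anks6 (0.887) and Glis3 (0.945), while replicate 3 stood lowest for Cldn11 (0.927). Resilient replicate 2 stood highest for Nfatc2ip (0.884) and replicate 3 for Gm13340 (0.901). Non-defeated replicate 1 stood highest for Pcsk5 (0.877), Hcn4 (0.863) and Abcc4 (0.857), replicate 2 for Col3a1 (0.884) and Anks6 (0.885) and replicate 4 for Terb1 (0.936) and Cox7c (0.924). Non-defeated replicate 2 stood lowest for Kat6a (0.874), and replicate 3 for mt-Cytb (0.844) and for genes with a read, 15510 against 16340 to 16440 (0.892).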

How the results depend on the processing

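Alternatives chosen after seeing the data were edgeR's quasi-likelihood test, both other pseudocounts, no composition scaling, mitochondrial genes left out, the 3 libraries of lowest correlation left out and all those of the mitochondrial share. The edgeR test was the one first written for raw counts, and only its use on recovered reads was chosen later. Of 4907 values of named genes under the alternatives, 4642 kept direction and side of the threshold, 156 lost the call, 80 gained it and 29 reversed. Most named genes had not passed at first, so for them keeping the side means staying uncalled. Only genes that had passed could lose the call. Between susceptible and resilient mice Capn3 lost it in 22 settings and kept it in 6, and mt-Atp6 in 18 and 9. For mt-Rnr1 these were 15 and 12 there, and 13 and 14 for resilient against non-defeated mice. Of 437 values of called lists, 373 kept both, 59 lost the call and 5 reversed. The cause was not tested for any value below. Leaving out libraries or fitting fewer groups also leaves fewer samples, and leaving out mitochondrial genes removes all genes called but Capn3. At the lowest depth 1 CPM stands for at least 33 reads. With 4 libraries per group simulated data gave back 14% to 18% of genes changed 2-fold and 55% to 66% of those changed 4-fold. All of these averaged at least 1 CPM.

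Genes called, in the order susceptible against non-defeated, resilient against non-defeated, susceptible against resilient and defeated against non-defeated (0, 1, 8 and 0), were 23, 91, 38 and 35 by DESeq2 and 0, 8, 16 and 0 by limma voom with sample quality weights. They were 0 in all 4 without the robust step and by edgeR's quasi-likelihood test, and 0 in the 3 pairwise comparisons with only the groups compared, a setting not run for defeated mice (606, 1222, 601 and 979 genes had an unadjusted p under 0.05 by limma-trend). Resilient against non-defeated became 2 with median-of-ratios size factors, no filter, the strict filter or no composition scaling and 0 with the title letter. Susceptible against resilient became 1 with a pseudocount of 0.25 CPM and 0 with 5 CPM. Without mitochondrial genes both became 0, as all genes called but Capn3 were mitochondrial and so were left out themselves. Without the 3 libraries they became 0 and 2. Left-out libraries gave 0 to 0, 0 to 9, 0 to 10 and 0 to 0.

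With the replicate block the genes called were 0 in each comparison. The samples share only a number: over 12 same-number pairs the deviations correlated from -0.277 to 0.196, 4 were over 0.1, and 3 of 12 libraries correlated best with their own number. The block also ended the heat shock call (camera, adjusted p = 0.0733) and no other list's.

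Lists called (2, 6, 6 and 6) were 0, 0, 1 and 0 with an estimated correlation, and 4 for susceptible against non-defeated and 2 for susceptible against resilient without the 3 libraries. Left-out libraries gave 2 to 8, 4 to 9, 2 to 10 and 4 to 9. The fold changes' correlation was 0.064 with the controls split and 0.486 to 0.691 over left-out libraries.

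Differences of the interaction ratio over left-out libraries ran from -1.06 to -0.817 for susceptible against non-defeated, -0.294 to 0.108 for resilient against non-defeated and -1.04 to -0.653 for susceptible against resilient mice (exact permutation p up to 0.0571, without resilient replicate 4). As differences of medians the first and last were -0.825 and -0.6 (exact permutation p = 0.0571 for both). The near-0 one turned to 0.108 and 0.0183 without non-defeated replicates 2 and 4 and to 0.0592, 0.0925 and 0.0525 without resilient replicates 1, 2 and 3. The mitochondrial share of susceptible less non-defeated mice turned to -0.533 for medians, -0.289 without non-defeated replicate 3 and -0.397 without susceptible replicate 4, and ran up to 1.14 over left-out libraries; that of susceptible less resilient mice was 4.76 for medians (exact permutation p = 0.0571).

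With the title letter these reversed: Mmp2 for susceptible (-0.67) and all defeated mice (-1.49), and for resilient mice Pcsk5 (-0.0589), Acan (-0.41), Hcn2 (-1.09), Ppp2ca (-1.13), Klf9 (-0.20), Olig2 (-0.50), Cspg5 (-0.53) and Syn2 (-0.18). With a pseudocount of 0.25 CPM Mmp2 for resilient mice became 0.24. Without the 3 libraries Mmp2 became -0.48 for susceptible and -0.72 for all defeated mice, Mmp14 -0.59, -0.11 and -0.35 for susceptible, resilient and all defeated mice, Ndufs5 0.0891 for resilient, and Cox8a 0.0161, Ndufs6 0.0365 and Cox6c 0.097 for all defeated mice. The ribosomal list of susceptible mice reversed there (camera, adjusted p = 0.815), as did oxidative phosphorylation for resilient (2.33e-05) and all defeated mice (4.35e-08) and susceptible against resilient mice (0.858). Over left-out libraries these ran through 0: Mmp2 from -0.49 to 0.48 for resilient and -0.24 to 0.74 for all defeated mice, Mmp14 from -0.0664 to 0.71 for susceptible mice and Furin from -0.21 to 0.38 for susceptible against resilient mice. Mmp2 for resilient mice turned to 0.0852, 0.48, 0.12 and 0.0592 without non-defeated replicates 1 and 2 and resilient replicates 1 and 2, and Furin to -0.13, -0.0883 and -0.21 without susceptible replicates 1 and 4 and resilient replicate 3. Oxidative phosphorylation for susceptible against resilient mice reversed without resilient replicate 4 (camera, adjusted p = 0.847, from 3.88e-05 upward over left-out libraries).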

Other observations

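Which values are given here was chosen after they were seen, from lists fixed beforehand. Meningeal and perivascular fibroblast markers were not called in susceptible against non-defeated mice (12 of 14 measured, 7 positive, median 0.09, mean -0.05, camera adjusted p = 0.979). Islr alone rose adjusted over that list alone, from 1.23 ± 1.26 to 5.29 ± 1.80 CPM (SD, n = 4 each), and 0 passed over all genes. Endothelial and mural cell markers were not called in resilient against non-defeated mice (15 of 17 measured, 13 positive, median 0.45, camera adjusted p = 0.0766). Resilient replicate 4 had an endothelial score of 2.15, where the other libraries ran from -0.86 to 0.29.

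Oligodendrocyte precursor markers were not called in resilient against non-defeated mice (10 measured, 7 positive, median 0.32, camera adjusted p = 0.199). Olig2, a transcription factor of the oligodendrocyte lineage, was at 2.19 ± 0.77 and Cspg5, a chondroitin sulfate proteoglycan gene, at 1.18 ± 0.50 (log2, SE), and neither passed. Scores followed the title letter within the susceptible group, at -0.58 and -0.60 in the libraries with the letter H and 0.51 and 0.46 in those with the letter N.

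Of 17416 genes in the authors' deposited table, 851 had a p under 0.05 over the 3 groups, where chance gives 871. Its correlation with the interaction ratio, over 12 libraries whose susceptible group has lower ratios by construction, had a p under 0.05 for 1144 genes, 964 positive and 180 negative. Chance gives 871 here too, and genes are not independent. Resilient replicate 4 had the highest ratio, 2.24 against 1.08 to 1.20 in its group, and the most genes with a read, 17086. Its weight in these correlations was not tested. The correlation was -0.707 for Pcsk5 and -0.584 for Acan.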
